A study of Arabidopsis thaliana with 9 samples.

How the data were processed

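RNA was taken from 14-day-old whole Arabidopsis thaliana seedlings of the Columbia background. There were 3 groups of 3 libraries each, 9 libraries in all. They were wild type, a line carrying an RNA interference construct against SRT1 (RNAi), and a line overexpressing SRT1 (OX). SRT1 encodes a nuclear sirtuin, a member of the NAD-dependent protein deacetylases. Libraries were made with a TruSeq kit from total RNA, per the labels' protocols. The groups were taken from the sample titles.

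The reads were processed with TopHat2 version 2.1.1, Cufflinks version 2.2.1 and Cuffdiff against the TAIR10 genome, per the submitters' processing notes, which give no role, order or Cuffdiff version. The deposited tables have the column names of Cuffdiff output, per the file headers. The authors deposited 4 lists of genes and 2 tables of genes found in a pair of lists. Each list gives, per gene, a locus, the labels of 2 groups, 1 deposited FPKM value per group (fragments per kilobase of transcript, scaled to the mapped fragments), a log2 ratio of the second value over the first, a fold value, a p-value and a q-value, as deposited by the authors. The lists hold only genes that differed at least 2-fold between the 2 columns, the smallest ratio being 2.00, with a q-value of at most 0.0496. Genes that did not pass were not analysed here, so no list could be tested for enrichment over the genome, and an absence from a list is not evidence that a gene did not change.

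Because the tables hold 1 FPKM value per group and no value per library, no SD, no new test between groups and no interval could be computed. Sequencing depth is unknown, as no counts were used here. The p-values and q-values of single genes are those of the authors' deposited tables, and those of gene lists, overlaps and relations were computed here. The smallest p-value that occurs is 5e-05, and it was given to 607 of the 832 genes of the OX lower list and to 860 of the 1134 genes of the OX higher list, so it ranks few genes. The ratio of p to q in the authors' deposited tables gives the share of all tests with a p-value at or below a given one. At the largest listed p-value that share was 57.9% in the OX lower list and 50.2% in the list titled higher in RNAi. Nothing in the labels says that the libraries of a group came from separate plants or cultures.

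The planned tests of per-library values by limma on log2(FPKM + 1) could not be run, and the plan's other branch was used: the listed genes were counted per direction and their deposited values described. Folds printed here are ratios of the 2 deposited FPKM values of a gene, computed without a pseudocount, with the higher value on top. A signed log2 value is that of the first column over the second. The deposited fold columns were not used, because they differ in kind between lists. In the OX higher list the column is a score made by the authors from the log2 ratio before deposit, equal in size to 2 times that ratio in 1134 of 1134 genes. In the list titled lower in RNAi it is the fold with a minus sign, in 377 of 377 genes, and in the OX lower list the fold, in 832 of 832 genes. Loci are in TAIR10 coordinates as deposited, counted here from 1. Gene span here is the length of the deposited locus and not of the transcript. A locus can cover more than 1 gene, as for RPL22 and RPS3. Of the listed entries, gene identifiers were looked up in a RefSeq annotation of TAIR10.1 for names and products only, where 745 of 832, 1129 of 1134, 672 of 749 and 376 of 377 identifiers of the OX lower, OX higher, titled higher and titled lower lists were found. The rest were almost all organelle genes, for which the names in the deposited tables were used. Close copies such as LHCB1.1 and LHCB1.2 or GSTF6 and GSTF7 share sequence, so the split of reads between them is uncertain.

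Before the data were examined, 23 gene lists with 410 entries and 21 families defined by gene symbol were fixed. For each list with at least 5 listed members, the members' directions were compared with those of the other listed genes by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over the tested lists of that comparison. The genes present in both comparisons were tabulated by direction and tested with a two-sided Fisher exact test. Spearman's rho and Pearson's r across genes used 100000 permutations, within each direction separately, because the listed genes fall into separate clusters. Genes are not independent replicates, so these p-values describe the lists and not plants. The direction test was checked on simulated lists. With the 1966 listed OX genes, lists of 10 genes drawn from 1 direction were called in 100% of runs, and any of 10 random lists was called in 8.5% of runs. With the 1126 listed RNAi genes these shares were 100% and 2.0%. The lists from 1 direction were drawn from the OX lower genes and from the genes titled lower in RNAi, the smaller side of each comparison. The larger sides were not checked. A list with 10 of 10 listed members titled higher in RNAi had p = 0.036 (Fisher exact) before adjustment. Unchanged lines compared with the same 3 control libraries were simulated for 200000 genes at a p threshold of 0.05 without adjustment, which is not the rule of the lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

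The named genes follow a rule fixed before the data were examined. They are, per list, the 8 genes with a symbol and the largest fold among those with both values above 0 and a higher value of at least 5 FPKM; per overlap, the 8 genes with the largest smaller fold under the same limits; up to 4 members with the largest fold of each fixed list with at least 3 listed members; and SRT1. Some genes that this rule takes are not reported here. FUM2, AT4G12500, AT5G56350, AT1G32440, NRT1.5 and the genes named from product groups do not follow this rule and were chosen after their values were seen. Other settings chosen before the data were examined were fold limits of 1 and 1.5 on the log2 scale, a q-value of at most 0.01, minimum values of 1 and 5 FPKM, a pseudocount of 1, leaving out genes with a value of 0, families in place of lists, and matching overlaps by symbol. Settings added after seeing the data were leaving out irregular genes, leaving out organelle genes, taking the RNAi direction from the shared column, and comparing directions within 10 classes of gene span. In the last, the listed genes of a comparison were cut into 10 equal groups by span, and the exact chance of the number of lower members was taken with directions shuffled within each group, two-sided, with Benjamini-Hochberg adjustment over the tested sets. An entry was called irregular if its locus was typed with spaces, if its log2 ratio differed from its own 2 values by more than 0.001, or if its second value differed between the OX and RNAi tables by more than 0.5 on the log2 scale after 1 common offset. These criteria and their limits were set after the data were seen. All 16 irregular genes met 1 of the first criteria, 15 by a spaced locus and SRT1 by its ratio, so the comparison of the second values did not by itself remove any gene from the 569 regular ones. The explanations weighed at the end, with the limits of their tests, were also written after the values were seen.

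Gene groups by product name were chosen after the lists were read. In all, 25 patterns of product names were tried, and all 25 are counted here, so that the adjustment covers every group looked at: 15 had at least 5 listed genes in OX and 11 in the RNAi tables.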

Results

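Transcript levels were measured by RNA sequencing in 14-day-old Arabidopsis seedlings of wild type, of a line carrying an RNA interference construct against SRT1 (RNAi) and of a line overexpressing SRT1 (OX), with 3 libraries in each of the 3 groups. The design compares each line with wild type, and the deposited overlap tables pair genes lower in OX with genes titled higher in RNAi, and genes higher in OX with genes titled lower in RNAi. The values are FPKM, 1 per group and gene, with no value per library, so no SD is given and every call of a difference is that of the authors' deposited table. Depth is unknown.

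The targeted gene, SRT1 (AT5G55760, chromosome 5, 22567222 to 22570963, a protein-coding gene), was 6.05 FPKM in OX and 1.75 FPKM in the column labelled wild type, 3.46-fold higher in OX. In the list titled lower in RNAi it was 2.37 FPKM in the group labelled RNAi and 0.419 FPKM in the group labelled wild type, which is 5.67-fold higher in the group labelled RNAi and goes against that label. The log2 ratio in the authors' deposited table for this entry has a size of 2.37, while its 2 values give 2.50. It was the only entry of the 377 whose ratio did not follow from its values, within 0.001. The column labelled wild type also differed for SRT1 between the OX and RNAi tables, 1.75 against 0.419 FPKM, a 4.18-fold difference.

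The labels of the RNAi tables conflict with each other. In the list titled higher in RNAi, the first column is labelled wild type and the second RNAi, and the second is higher. In the list titled lower in RNAi, the first column is labelled RNAi and the second wild type, and the first is higher, so title and labels disagree. The second column of the RNAi tables was compared with the second column of the OX tables, which is labelled wild type. Over 569 genes listed in both comparisons and not irregular, the log2 ratio of these columns had a median of 0.08 and a median absolute deviation of 0.0081, and 569 of 569 genes lay within 0.1 of the median. The first columns of the OX and RNAi tables had a median absolute deviation of 0.447 over these genes. Within the RNAi tables, 46 of 46 p-values found in both lists had equal q-values in the authors' deposited tables, as had 58 of 58 in the OX tables. Of 75 p-values found both in the OX lower list and in the list titled higher in RNAi, 0 had equal q-values. Below, the second column is called the shared column, and RNAi directions are given as the level in the first column relative to it.

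**Figure D1:**
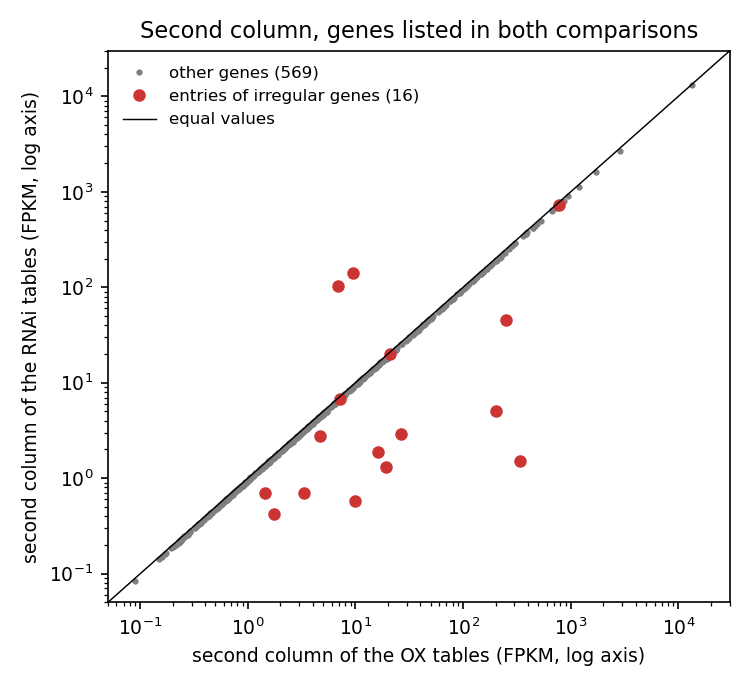
FPKM in the second column of the OX tables (horizontal, log axis) and of the RNAi tables (vertical, log axis), 1 point per gene listed in both comparisons. The 569 other genes follow a single line just under equality, and most of the 16 entries of irregular genes lie off it.

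In OX, 832 genes were lower and 1134 higher than in the shared column. Among genes with a symbol and at least 5 FPKM in the shared column, the 8 largest decreases were those of chloroplast-encoded genes. PSBK and PSBZ, which encode small photosystem II subunits, were 3.1 FPKM in OX against 728 FPKM and 7.82 against 1713 FPKM, 235-fold and 219-fold lower. PSBH, also of photosystem II, was 102-fold lower, ATPH of the chloroplast ATP synthase 41.9-fold lower, the ribosomal protein genes RPS15, RPS19 and RPS18 were 145-fold, 68.1-fold and 39.9-fold lower, and YCF3, a photosystem I assembly factor, was 46.7-fold lower. The deposited q-values were 0.015 for PSBK and RPS15 and 0.0081 for YCF3, against 0.00015 for PSBZ. PSBK and PSBZ are short genes, at 7017 to 7202 and 35751 to 35939 of the chloroplast genome. Whether short length adds to these folds was not tested. In all, 56 chloroplast-encoded and 31 mitochondrially encoded genes were listed as lower in OX and 0 as higher, with median folds of 22.8 and 5.32, against 2.49 for the 745 nuclear genes of that list.

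The largest increase in OX was that of PCC1, a pathogen- and clock-responsive gene, at 10.7 against 0.434 FPKM, 24.7-fold. Among genes with a symbol and at least 5 FPKM in OX, it was followed by HMGB13, a high mobility group box protein, at 4.73-fold, CPX2, a coproporphyrinogen oxidase homologue, at 4.36-fold, AGL31 (MAF2), a floral repressor, at 4.1-fold, and PMI15, NFYC10, SR34B and CRWN3 at 3.97-fold, 3.86-fold, 3.79-fold and 3.72-fold. SR34B encodes a splicing factor and CRWN3 a protein of the nuclear lamina. The listed nuclear genes also differed in span. Leaving out irregular genes, the median gene span was 1309 bp for 731 genes lower in OX and 3234 bp for 1133 genes higher in OX (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 1e-05 over 2 comparisons).

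Of the 23 fixed gene lists, 3 had at least 5 listed members in OX, and all 3 differed in direction from the other listed genes. Root cell markers were lower in OX for 6 of 6 listed members of 12 (Fisher exact, adjusted p = 0.0085). With a log2 fold limit of 1.5, a minimum of 5 FPKM or folds from log2(FPKM + 1), 1 of the 6 was left and the list could not be tested. CASP1 and CASP5, which encode Casparian strip proteins of the endodermis, were 2.89-fold and 2.62-fold lower, and LRX1, a root hair wall protein, 2.25-fold lower. Antioxidant and glutathione S-transferase genes were lower for 5 of 5 listed members of 20 (adjusted p = 0.013), among them GSTF6 at 9.12 against 51.1 FPKM, 5.61-fold lower, GSTF3 at 4.35-fold, GSTF7 at 3.44-fold and GSTF8 at 2.35-fold. The adjusted p of this list was 0.071 with folds from log2(FPKM + 1), and with a log2 fold limit of 1.5 or a minimum of 5 FPKM 3 and 4 of the 5 were left and it could not be tested. The glycolysis list had 10 of 10 listed members lower in OX (adjusted p = 0.00054), of which 9 were irregular. PFK5 (phosphofructokinase), PKPbeta1 (AT5G52920, a plastid pyruvate kinase) and HXK2 (hexokinase) were 3.99-fold, 3.1-fold and 2.96-fold lower, all 3 of them irregular. The only member in a regular entry was FBA1, a plastid aldolase, at 414 against 1012 FPKM, 2.45-fold lower, and without irregular genes the list could not be tested.

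The other lists had too few listed members for a test in OX. The rapid touch and wound response list had 4 lower and 0 higher members. ZAT10, an irregular entry, was 3.74-fold lower, ERF6 was 2.67-fold, ZAT12 2.29-fold and ERF105 2.08-fold lower. Photosynthesis had 3 lower members, LHCB1.1 and LHCB1.2 of the light-harvesting complex at 2.27-fold and 2.25-fold and RBCS1B of Rubisco at 2.08-fold. Iron deficiency had 3 lower members, the peptide genes IMA3 and IMA2 at 2.94-fold and 2.14-fold and the regulator BHLH39 at 2.63-fold. The circadian clock had 3 higher members, the pseudo-response regulators PRR3, PRR9 and PRR7, at 3.28-fold, 2.74-fold and 2.32-fold. Members of other lists went both ways. CBF2, a cold-response regulator, was 3.94-fold lower and COR15B, a cold-regulated gene, 2.43-fold higher. RD29A was listed as 3.11-fold lower in an irregular entry and, under the symbol LTI78, as 2.18-fold higher in a regular one. PR2 (BG2), a glucanase induced in defence, was 8.46-fold higher, at 1.42 against 0.168 FPKM. PBS3 and CBP60G, which act in salicylic acid synthesis and its control, were 2.44-fold and 2.37-fold lower. VSP2, a jasmonate-induced storage protein, was 2.27-fold higher and the ethylene synthesis gene ACS2 3.98-fold lower. MYB29, a regulator of aliphatic glucosinolates, was 2.72-fold higher and MYB51, a regulator of indolic ones, 2.22-fold lower. FLC, a floral repressor, was 2.26-fold lower. The tricarboxylic acid cycle had FUM2 higher, auxin response had 2 higher members, and sugar starvation and phosphate starvation had 1 lower member each. The lists of other histone deacetylases, fermentation and hypoxia, alternative respiration, heat shock, flavonoids and anthocyanins, senescence and seed storage markers had 0 listed members in OX.

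Of the 21 families, 13 could be tested in OX and 7 passed, all with more members lower than higher. Only genes with a symbol could be members, while the test compared them with all listed genes. In OX, 458 of 832 lower and 492 of 1134 higher genes had a symbol, which favours the lower side. In the RNAi tables, 405 of 749 titled higher and 181 of 377 titled lower had one. The tests of families did not take this into account. ERF and DREB transcription factors had 13 lower and 1 higher member (Fisher exact, adjusted p = 0.00073), UDP-glycosyltransferases 8 and 0 (adjusted p = 0.0033), glutathione S-transferases 7 and 0 (adjusted p = 0.0062), arabinogalactan proteins of the cell wall 8 and 0 (adjusted p = 0.0033), cytochrome P450s 14 and 4 (adjusted p = 0.0066) and calmodulin-like proteins 5 and 0 (adjusted p = 0.025). Ribosomal proteins had 17 lower and 0 higher members (adjusted p = 5.3e-06), but 15 of the 17 were encoded in the chloroplast or mitochondrial genome, so this family repeats the organelle result. Because short genes were mostly lower in OX, the families were also compared within 10 classes of gene span, a test added after the result was seen. Cytochrome P450s (adjusted p = 0.0064 over 13 families), UDP-glycosyltransferases (0.033) and ribosomal proteins (0.021) still passed. ERF and DREB factors (0.45) did not. They could not have passed after adjustment even with all members lower, so gene span and family were not separated for them. Glutathione S-transferases, calmodulin-like proteins and arabinogalactan proteins could not have passed, since with all members lower the smallest p they allow is 0.054, 0.090 and 0.18, so gene span and family were not separated for these 3. The 3 fixed lists passed in this test too, root cell markers and antioxidant genes each with adjusted p = 0.032 and glycolysis with 2.4e-07. Only 1 of the 10 listed glycolysis members was a regular entry, so that list could not be tested here without irregular genes. The antioxidant list shares GSTF3, GSTF6, GSTF7 and GSTF8 with the glutathione S-transferase family. MYB, NAC and bHLH factors, cysteine-rich receptor-like kinases, receptor-like proteins and lipid transfer proteins did not pass, with adjusted p-values from 0.803 to 1.0.

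**Figure D2:**
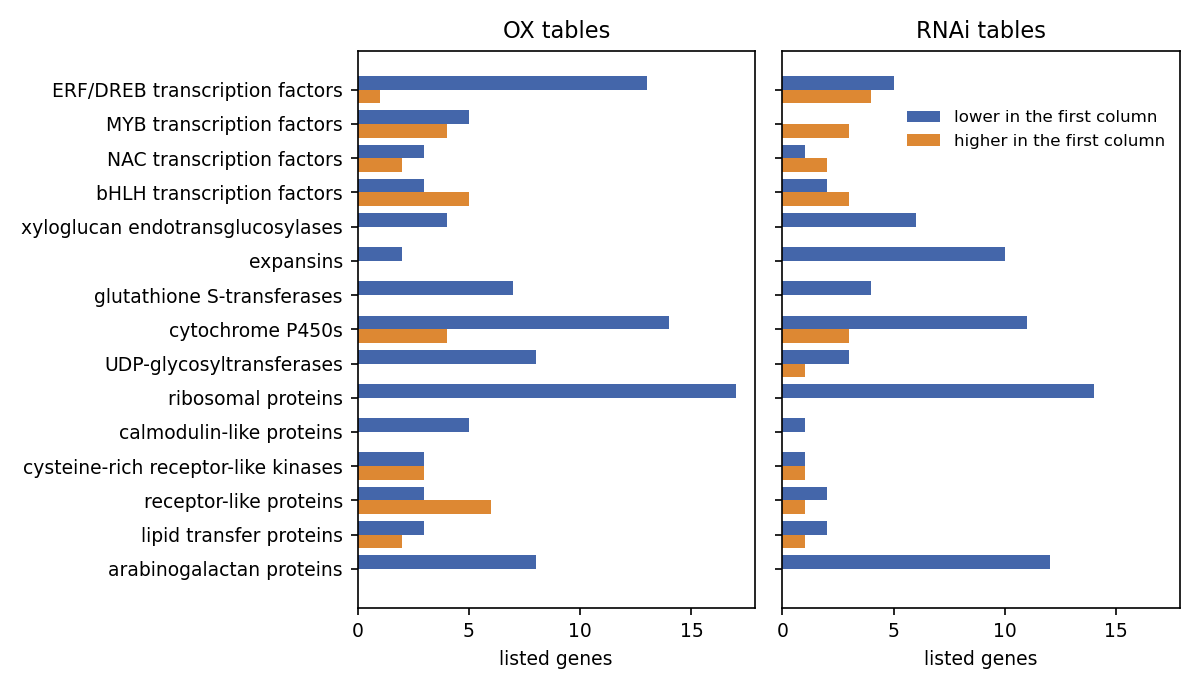
Number of listed genes (horizontal axis, from 0) of each family with at least 5 listed members in the OX or the RNAi tables, lower (blue) or higher (orange) in the first column than in the shared column. ERF and DREB factors had 13 lower and 1 higher gene in the OX tables and 5 lower and 4 higher in the RNAi tables, and expansins had 2 and 10 lower genes.

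In the RNAi tables, 749 genes (titled higher in RNAi) were lower in the first column than in the shared column and 377 genes (titled lower) were higher. The list of 749 held 55 chloroplast and 21 mitochondrial genes, with median folds of 5.35 and 2.80, and the list of 377 held 0. The chloroplast ribosomal protein genes RPS19, RPL16, RPL22, RPL14 and RPS3 had large folds, from 16.1-fold for RPS19, at 11.7 against 189 FPKM, to 13.4-fold for RPS3, with YCF1.2 at 13.0-fold. AIR1, an auxin-induced root gene of the lipid transfer family, was 14.9-fold lower than in the shared column, at 3.68 against 54.8 FPKM. The largest fold of this list was that of AT4G12500, a lipid transfer protein gene without a symbol, at 30.7-fold. In the list of 377, among genes with a symbol and at least 5 FPKM in the first column, PCC1 had the largest fold and was 16.8-fold higher than in the shared column. The seed maturation genes EM6, SESA5 and PAP85 were 14.6-fold, 5.17-fold and 5.0-fold higher, and LAL5, WRKY26, LURP1 and BCAT2, a branched-chain aminotransferase, were 4.41-fold, 3.70-fold, 3.65-fold and 3.35-fold higher. Median spans were 1550 bp for 658 nuclear genes lower and 2370 bp for 376 genes higher than the shared column (permutation p = 1e-05).

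Of the fixed lists, 2 could be tested in the RNAi tables and 0 passed. With all listed genes, every listed member of both was lower than the shared column. Neither could therefore have passed on that side with its number of members, and the difference from OX is not a result. The glycolysis list had 10 of 10 listed members lower than the shared column (Fisher exact, adjusted p = 0.073), all 10 irregular, including HXK1, HXK2, PFK5 and PFK1 at 3.27-fold, 3.12-fold, 2.80-fold and 2.36-fold. Its adjusted p was 0.034 without organelle genes and 0.0013 within 10 classes of gene span, and 0 of its members were left without irregular genes. Root cell markers had 7 of 7 lower (adjusted p = 0.10), among them LRX1, the wall protein gene PRP3, the root hair expansin EXP18 and CASP5, at 5.26-fold, 3.99-fold, 3.72-fold and 3.28-fold. The values were low, LRX1 being 0.244 against 1.28 FPKM and CASP5 0.351 against 1.15 FPKM. Seed storage markers had 4 listed members, all higher than the shared column, SESA3, SESA5, OLEO2 and OLEO1, at 7.07-fold, 5.17-fold, 3.01-fold and 2.2-fold. Here too values were low, SESA3 being 0.987 against 0.140 FPKM (deposited q-value 0.039), OLEO2 2.12 against 0.703 FPKM and OLEO1 1.70 against 0.772 FPKM. The clock genes PRR3, PRR5 and PRR9 were 2.67-fold, 2.15-fold and 2.12-fold higher. Jasmonate genes VSP2, VSP1 and JAZ5 were 3.32-fold, 2.50-fold and 2.08-fold higher and ACS2 was 2.12-fold lower. PR2 was 10.5-fold higher, at 1.67 against 0.159 FPKM, and CBP60G and PBS3 were 2.34-fold and 2.14-fold lower. GSTF6, GSTF7 and GSTF8 were 4.23-fold, 2.95-fold and 2.19-fold lower, and CSD2, a superoxide dismutase, 2.03-fold higher. NCED3, an abscisic acid synthesis gene, and CBF2 were 2.78-fold and 2.70-fold lower, RD29A, an irregular entry, 2.23-fold lower and RD29B 4.04-fold higher. MYB29 and MYB76 were 2.98-fold and 2.13-fold higher. LHCB2.4 and LHCB1.2 were 2.57-fold and 2.30-fold lower, FT, which promotes flowering, 2.61-fold higher and FUL 3.28-fold lower. ZAT10, an irregular entry, and WRKY53 were 5.53-fold and 2.01-fold lower. Heat shock had 2 members higher, other histone deacetylases and flavonoids 1 member lower each, and sugar starvation, senescence and phosphate starvation 1 member higher each. The lists of fermentation and hypoxia, tricarboxylic acid cycle, alternative respiration, iron deficiency and auxin response had 0 listed members. Of 7 families tested, ribosomal proteins (14 lower, 0 higher, all 14 encoded in organelle genomes; adjusted p = 0.027) and arabinogalactan proteins (12 lower, 0 higher; adjusted p = 0.039) passed. Within 10 classes of gene span neither could have passed, the smallest p with all members lower being 0.069 and 0.074. Expansins had 10 lower and 0 higher members (adjusted p = 0.085, 0.045 without irregular genes and 0.17 within 10 classes of gene span). With all members lower, 0.085 and 0.17 were the smallest adjusted p-values they could reach on that side, so the 0.17 does not show an effect of span. ERF and DREB factors had 5 lower and 4 higher members (adjusted p = 0.49).

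Both comparisons listed 584 genes, in 585 pairs of entries because RD29A is in both OX lists. Of the 585, 358 were lower in OX and titled higher in RNAi, 215 were higher in OX and titled lower in RNAi, 11 were lower in OX and titled lower in RNAi, and 1 was higher in OX and titled higher in RNAi. By the titles, 97.9% were thus opposite between the lines. By the shared column, the same 573 pairs moved the same way in both tables, and 12, or 2.05%, moved in opposite ways. The directions in the 2 comparisons were associated (two-sided Fisher exact p = 7.9e-146, genes not being independent). In simulated unchanged lines compared with the same 3 control libraries, 97.3% of the genes called in both comparisons moved the same way. The simulation used a p threshold of 0.05 without adjustment and not the rule of the lists. Shared libraries can thus give a high share, and the observed share does not by itself show a common response. The overlap that independent lists would give needs the number of genes tested, which is not known. The simulated unchanged lines overlapped 3.64 times as often as independent lists would, so the overlap was not tested against chance.

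Among genes with a symbol and at least 5 FPKM, those with the largest changes in both comparisons and lower than the shared column included the chloroplast genes RPS19, RPL16, RPL22, RPL14, RPS3, YCF1.2 and RPOA, a subunit of the plastid RNA polymerase. RPL22 and RPS3 have the same deposited locus, 82826 to 83949, and nearly equal values, 6.96 and 6.76 FPKM in OX, so they may not be separate observations. RPOA was 22.6-fold lower in the OX table and 11.5-fold lower in the RNAi table. Of the genes higher than the shared column, PCC1 led, followed by LAL5 (3.19-fold in the OX table, 4.41-fold in the RNAi table), LTP3, a lipid transfer protein (2.95-fold and 2.55-fold), the Mediator subunit gene MED9 (2.86-fold and 2.51-fold), AAE16 (2.43-fold and 2.50-fold), the invertase gene INVC (2.35-fold and 2.4-fold), SCPL13 (3.40-fold and 2.29-fold) and AGL31 (4.1-fold and 2.28-fold). Across the 358 genes lower than the shared column, fold sizes in the 2 tables had Spearman's rho of 0.543 and Pearson's r of 0.590, and across the 215 higher genes 0.337 and 0.573 (each permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 1e-05 over 2 relations). These are relations across genes, which are not independent replicates, and part of them comes from the shared column. Unchanged simulated lines gave rho of 0.295 among genes called lower in both, at a p threshold of 0.05 and not by the rule of the lists. Without organelle genes, rho of the lower genes was 0.352 over 283 genes. With folds from log2(FPKM + 1), rho of the higher genes was -0.05 over 39 genes. The deposited overlap tables hold 358 and 215 genes, and all 358 and 215 were found again by matching the lists on gene identifier.

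**Figure D3:**
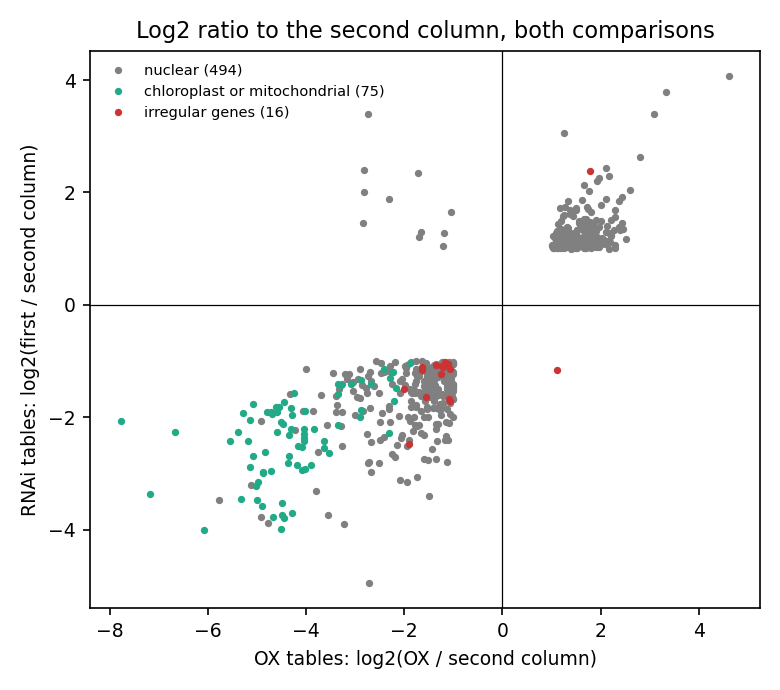
Log2 ratio of the first column to the shared column in the OX tables (horizontal) and the RNAi tables (vertical), 1 point per pair of entries. The 358 pairs at lower left and 215 at upper right move the same way relative to the shared column, and the other 12 lie in the other quadrants; the 75 chloroplast and mitochondrial genes all lie at lower left.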

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

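No paired analysis was possible because the deposited tables give 1 value per group, and for the same reason no replicate could be left out and no count test or pseudocount of 0.1 could be run. Leaving out genes with a value of 0 moved nothing, as 0 genes had one. A log2 fold limit of 1 could not move anything either, since only genes of at least 2-fold are listed. A q-value of at most 0.01 and a minimum of 1 FPKM kept each count within 1.5 times of its value. Matching by symbol gave overlaps of 356 and 215. The share of pairs titled opposite stayed between 97.3% and 99.3% in every setting that left out genes. Taking the RNAi direction from the shared column, a setting added after seeing the data, reversed it, to 2.05%.

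The counts fell with stricter limits, which by construction leave fewer genes. With a log2 fold limit of 1.5, 342 genes were lower and 334 higher in OX, 281 were titled higher and 91 titled lower in RNAi, the overlaps were 155 and 28, and 0 fixed lists passed in OX. With a minimum of 5 FPKM these counts were 499, 444, 359, 131, 201, 65 and 1. With folds from log2(FPKM + 1) and a limit of 1 they were 491, 383, 345, 105, 199, 39 and 1, the passing list being glycolysis in both settings, and rho of the higher genes turned to -0.052 (permutation p = 0.749). The cause of that turn was not tested. In place of 3 fixed lists in OX and 0 in RNAi, where the tested lists could not have passed on the side they were on, 7 and 2 families passed. Within 10 classes of gene span, added after seeing the data, 3 and 1 fixed lists passed, the latter being glycolysis, and 3 and 0 families. Without organelle genes, added after seeing the data, 1 fixed list passed in RNAi, glycolysis, whose entries there are all irregular. Unknown depth limits the low values most: 86 of the 832 and 188 of the 1134 OX genes had a higher value below 1 FPKM.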

Other observations

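The tests in this part were all chosen after the lists and results were seen. Of 25 gene groups tried by product name in the annotation, 15 had at least 5 listed genes in OX and 11 in the RNAi tables, and p-values are adjusted over those 15 and 11. Extensins, structural proteins of the cell wall, had 22 genes lower and 0 higher in OX (Fisher exact, adjusted p = 7.8e-08) and 21 lower and 0 higher than the shared column in the RNAi tables (adjusted p = 0.0026), with 18 genes in both. The extensin gene ATEXT4 was 75.2 against 675 FPKM in OX, 8.97-fold lower. Some listed extensins had nearly equal values in OX, AT1G23720 at 6.62 against 19.8 FPKM and AT3G28550 at 6.74 against 19.8 FPKM. Whether such genes share reads was not tested. If they do, they are not separate observations, and the p-values of this group here and below are too small. Root cell markers were also lower for 6 of 6 listed members in OX and 7 of 7 in the RNAi tables, LRX1 being in both sets, so a lower share of root tissue was not separated from a change of these genes. Class III peroxidases had 11 lower and 0 higher in OX (adjusted p = 0.00056), with PER71 at 25.0 against 298 FPKM, and 10 lower and 0 higher in the RNAi tables (adjusted p = 0.067). Lipid transfer proteins had 17 lower and 4 higher in OX (adjusted p = 0.0016) and 20 lower and 2 higher in the RNAi tables (adjusted p = 0.033), with AT4G22470 30.1-fold lower in OX. The seed storage pattern, 13 lower and 2 higher in OX (adjusted p = 0.0019) and 18 and 3 in the RNAi tables (adjusted p = 0.088), has the same leading genes, because their product name holds both terms. Arabinogalactan products had 8 lower and 0 higher in OX (adjusted p = 0.0022) and 12 and 0 in the RNAi tables (adjusted p = 0.033).

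Late embryogenesis abundant proteins had 8 lower and 2 higher genes in OX (adjusted p = 0.032), with LEA18 and M17 33.4-fold and 30.5-fold lower, and 8 lower and 9 higher in the RNAi tables (adjusted p = 0.14). Receptor-like kinases and leucine-rich repeat proteins had 11 lower and 13 higher in OX (adjusted p = 0.84) and 20 lower and 2 higher in the RNAi tables (adjusted p = 0.033), with the senescence-induced kinase SIRK 13.6-fold lower. Groups that did not pass were MADS-box factors (2 lower and 5 higher in OX, adjusted p = 0.76; 1 and 4 in the RNAi tables, adjusted p = 0.072), DNA polymerases (1 and 4 in OX, adjusted p = 0.50), hypothetical proteins (4 and 3 in OX, adjusted p = 0.54), and, in the RNAi tables, expansins by product name (9 and 0, adjusted p = 0.067), xyloglucan enzymes (6 and 0, adjusted p = 0.21) and aquaporins (5 and 1, adjusted p = 0.67). The class III peroxidases, expansins and xyloglucan enzymes of the RNAi tables were all lower, so they could not have passed on that side. Oleosins, defensins and thionins, chromosome structural maintenance, NBS-LRR, histone superfamily, nuclear matrix and RecQ proteins had fewer than 5 listed genes in each comparison.

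Helicases had 15 genes higher and 0 lower in OX (adjusted p = 0.0015), among them INO80, a chromatin remodeller, at 15.3 against 6.13 FPKM and RECQL3 at 3.14 against 1.13 FPKM. Myosins and proteins named after them had 14 higher and 0 lower (adjusted p = 0.0016), kinesins 7 and 0 (adjusted p = 0.032), chromatin and histone products 10 and 0 (adjusted p = 0.011), and pentatricopeptide repeat proteins, which act on organelle RNA, 12 and 0 (adjusted p = 0.0035). The RNAi tables listed 0 helicases, kinesins and myosins and 4 pentatricopeptide repeat genes, all higher than the shared column. The helicases and kinesins listed in OX are long genes, with median spans of 7137 and 7679 bp. Genes of at least 3000 bp made up 9.44% of the nuclear genes lower in OX and 55.6% of those higher, and 12.5% and 35.9% of those lower and higher than the shared column in the RNAi tables.

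Direction in OX followed gene span, so the groups were also compared within 10 classes of gene span. Extensins (adjusted p = 3.9e-06) and class III peroxidases (0.0052) still passed in OX, and extensins (0.0040) and receptor-like kinases and leucine-rich repeat proteins (0.0022) in the RNAi tables. No other group passed. In OX the adjusted p was 0.88 for lipid transfer proteins, with a median span of 829 bp, 0.38 for arabinogalactan products, 0.38 for the seed storage pattern, 0.61 for late embryogenesis abundant proteins, 0.82 for helicases, 1 for kinesins, 0.20 for myosins, 0.61 for chromatin and histone products and 0.067 for pentatricopeptide repeat proteins. In the RNAi tables it was 0.18 for lipid transfer proteins. The helicases, kinesins, myosins, chromatin and histone products, pentatricopeptide repeat proteins and arabinogalactan products in OX, and the class III peroxidases, expansins, xyloglucan enzymes and arabinogalactan products in the RNAi tables, could not have passed after adjustment even with all members on the side they were on, so gene span and function cannot be separated there.

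The first pattern is the opposite direction of 573 pairs by the titles of the lists. An opposite response of the lines, each measured against the libraries labelled wild type in its own table, is argued against by the list titled higher, where that column is labelled RNAi: 344 of its 344 regular genes that OX also lists as lower lay within 0.1 of the OX shared column on the log2 scale, after 1 common offset. The median absolute deviation of 0.0081 is consistent with the same libraries carrying different labels in the 2 RNAi tables. Which libraries they are cannot be told apart, because SRT1, the gene taken to check the labels, differs by 2.06 on the log2 scale between the shared columns. If they are wild type, as 3 of the 4 lists label them, the 573 pairs lay on the same side of wild type in both lines. As both are ratios to that 1 column, a change in both lines was not separated from a shift of the shared libraries. If they are the RNAi line, the OX tables compare OX with RNAi.

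The second pattern is the glycolysis list. Loci typed with spaces occur in 14 entries of the OX lower list, 14 of the list titled higher in RNAi and 0 of the others, and 27 of these 28 give exactly the start and end of the reference annotation, against 4 of 2894 other entries as written and 208 with 1 added to the start. Of the 15 irregular genes present in both comparisons, 12 had shared columns more than 0.5 apart on the log2 scale. Of 569 other genes, 0 did. The difference was up to 223-fold, for AT5G56350. Values from another run would differ in this way, but the q-values do not show one. At a p-value of 5e-05, irregular entries had the same deposited q-values as other entries, 0.00015 in OX and 0.00020 in the RNAi tables. In the RNAi table the locus given for AT1G32440, a pyruvate kinase, covers 0.40% of that gene and 99.6% of its neighbour NRT1.5. The other 3 of the 15, HXK2, ENO2 (AT2G36530) and AT4G26390, are all of the glycolysis list and were lower in both comparisons. Their shared columns differed by 0.10, 0.066 and 0.092 on the log2 scale, near the median of 0.08 of regular genes. Their loci were typed with spaces as well. Whether glycolysis genes changed stays open, since regular entries of the list number 1, FBA1, and genes outside the lists were not analysed here. Where the irregular values come from was not tested.

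The third pattern is the lower level of organelle transcripts in both first columns relative to the shared column. As both are ratios to that 1 column, they do not separate a fall in the first columns from a rise in the shared column. A response of chloroplasts alone is argued against by the 31 mitochondrially encoded genes lower in OX. Chloroplast folds span 1.74 on the log2 scale, from 13.3-fold at the 10th to 44.2-fold at the 90th percentile, but without a spread per value this does not decide on carry-over of RNA without poly(A) tails by 1 common factor. Such carry-over, carry-over that differs by transcript and a change with the genotype cannot be told apart, since all allow the 75 organelle genes lower than the shared column in both comparisons, and no values per library were used. All 75 had the larger fold in OX, with medians of 20.5 and 4.80.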
